A study of Homo sapiens with 12 samples.

How the data were processed

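RNA was measured in 12 cultures of HLF cells, an established human hepatocellular carcinoma line by general knowledge (the labels give only its name). Each of 3 groups held 4 libraries: a nonsense siRNA control (siCo), and 2 combinations of siRNAs against YAP1 and TAZ, the product of the gene WWTR1. The combinations siYAP/TAZ#1 and siYAP/TAZ#2 use different siRNAs for both genes. Per the labels' protocols, RNA was taken 24 h after transfection, samples had a RNA integrity number above 7, and sequencing used a BGISEQ platform. The design text calls the replicates biological; how the cultures were separated is not described, so p-values measure the spread between these libraries.

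Per the submitters' processing notes, Trim Galore 0.6.4, kallisto 0.4.6 and the genome build hg19 were used, with no role or setting given. The authors deposited, for each library, a table of estimated counts per Entrez gene and a table of TPM (transcript abundance corrected for length and depth) for the same genes. Between 41.3% and 44% of the genes of a library held a value that was not whole (by over 1e-06), so counts were rounded to whole numbers before testing, which moved at most 0.011% of a library's total. How transcript estimates were summed to genes, and whether counting used strand, is not given in the sources used here. Antisense genes, read-through genes, pseudogenes and near-identical family members can share reads with other genes, so their values are uncertain.

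Of the 23101 Entrez IDs in the files, 23078 were matched to symbols and biotypes of a RefSeq gene table on the assembly GRCh38.p14. The 23 others held at most 0.0978% of a library's counts. Because that assembly differs from the authors' build, no coordinates are given, and the assembly served only for names, biotypes, which genes lie within others, and 3' UTR sequences (GENCODE v29).

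The main test was edgeR 4.0.16 (quasi-likelihood F-test, R 4.3.3) on the rounded counts, with TMM scaling, the filterByExpr filter and one fit of all 12 libraries with 3 groups. It tested 15602 genes, which held at least 99.96% of each library's counts. The contrasts were each combination minus siCo, and siYAP/TAZ#1 minus siYAP/TAZ#2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and counted as changed by both combinations when called in both contrasts with the same sign. Adjusted p-values of single genes below come from this test, and values after ± are standard errors of log2 fold changes or, for CPM (counts scaled to the TMM-adjusted library size), standard deviations over 4 libraries.

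Named genes follow a rule fixed before the data were examined. It takes YAP1 and WWTR1; the 12 largest rises and 12 largest falls shared by both combinations at a mean log2 CPM of at least 2, ranked by the smaller of the 2 changes; 8 lncRNA genes each way at a mean log2 CPM of at least 0; the 8 highest and 8 lowest genes in the direct contrast; and up to 4 members of each gene list. Of these lists, 17 were fixed before the data were examined, plus the 2 targets. They were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01), again with an estimated correlation, and with fry. Of the listed symbols, 3 had no match and 6 were matched through older symbols.

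Both combinations share the control libraries, so 20 data sets with no change were simulated from the control means and gene dispersions, and the controls were also split into 2 pairs. In simulated data of 15602 genes, 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold in siYAP/TAZ#1. The test recovered 68.7%, 83.6% and 97% of these, with 15 false calls among 181. With as many genes changed for siYAP/TAZ#2 the shares were 64.2%, 85.1% and 95.5%, with 9 false calls among 172, and for the direct contrast 74.6%, 82.1% and 100%, with 7 among 178. Far fewer genes were changed there than were called in the real data, so these shares need not hold for it. A simulated list of 25 genes changed 1.3-fold was found by camera, with 0 of 16 unchanged lists called. The simulation drew each gene independently, so it cannot show how often camera at the preset correlation calls unchanged lists whose genes vary together.

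All 7-mers were counted in the 3' UTRs of 13164 protein-coding genes with at least 50 bases of UTR. The share of genes with a 7-mer in a set was compared with the share in other genes of the same UTR length, in 10 length classes, by a one-sided binomial tail adjusted over 16384 7-mers. A normal tail was run first and replaced after its result was seen, because it called rare 7-mers; it gave 8 called 7-mers against 5 for genes lower with siYAP/TAZ#1, and 35 against 12 for genes lower with siYAP/TAZ#2, with the same leading 7-mers. In 5 simulated sets the planted 7-mer led each time, and sets without one gave 0 calls with the binomial and up to 2 with the normal tail.

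Alternatives fixed before the data were examined were DESeq2 size factors, other low-count filters, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), only the groups compared, glmTreat at 1.5-fold, the replicate number as a block, split controls for the correlation of the 2 profiles, and leaving out each library in turn. The counts of shared genes with split controls were added after seeing the data. Library totals without a composition factor and upper-quartile factors were added after seeing that TMM factors were 0.938 to 0.955 in the controls and 1.00 to 1.04 in the knockdowns. XIST and Y-linked genes were not named. Some single-gene results are not reported here.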

Results

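The data were gene-level read counts from 12 libraries of HLF cells, 4 with control siRNA, 4 with siYAP/TAZ#1 and 4 with siYAP/TAZ#2. YAP1 and TAZ are transcriptional co-activators of the Hippo pathway, and the series title names lncRNAs that depend on them. Library totals ran from 13.94 to 32.14 M counts, and 17845 to 18701 genes had counts above 0. The library siYAP/TAZ#1 replicate 3 was the shallowest and lay apart on the third principal component (8.38% of variance, at 28.9 against -16.8 to 10 for the others). Controls and knockdowns separated on the first component (36.4%), and the 2 combinations on the second (20%). Replicates of a group differed by more than counting noise, with a mean chi-square per gene of 4.28 to 56.7, so no library was a copy of another.

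Both combinations lowered both targets. YAP1 (Entrez 10413) stood at 224.4 ± 4.93 CPM in the controls, 19.9 ± 2.58 with siYAP/TAZ#1 and 23.5 ± 1.47 with siYAP/TAZ#2 (SD, n = 4), which is 8.77% and 10.4% of the control level. WWTR1 (Entrez 25937) fell from 421.6 ± 13.9 CPM to 33.7 ± 1.59 with siYAP/TAZ#1 and to 150.0 ± 7.97 with siYAP/TAZ#2, or 7.99% and 35.6% of control. The log2 fold changes were -3.51 ± 0.07 and -3.26 ± 0.07 for YAP1 (edgeR adjusted p = 1.4e-16 and 8.37e-17), and -3.65 ± 0.05 and -1.49 ± 0.05 for WWTR1 (6.81e-19 and 1.64e-14). WWTR1 was lower with siYAP/TAZ#1 than with siYAP/TAZ#2 by a log2 difference of -2.15 (adjusted p = 5.45e-16), so the combinations differ in how much WWTR1 mRNA they leave.

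**Figure D1:**
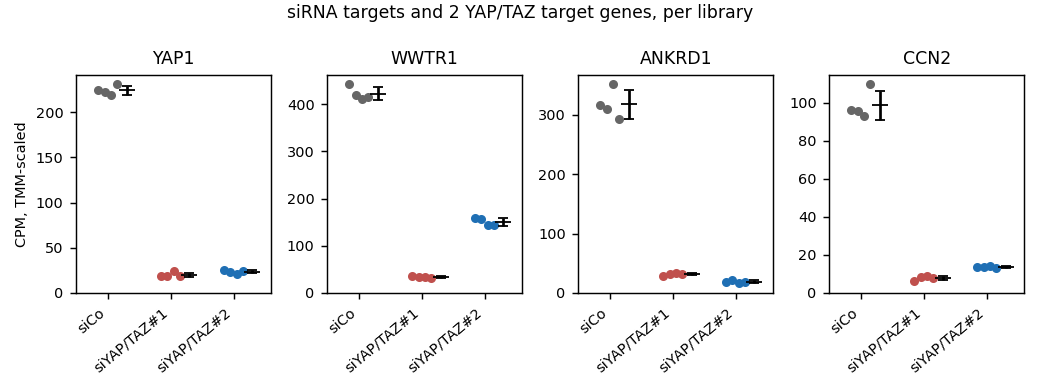
CPM with TMM scaling (linear axes from 0) of YAP1, WWTR1, ANKRD1 and CCN2 in each of the 12 libraries, by group; points are libraries and black marks are the mean with the SD of 4 libraries. All knockdown libraries lie below all controls, and WWTR1 is lower with siYAP/TAZ#1 (mean 33.7 CPM) than with siYAP/TAZ#2 (150.0 CPM).

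The first comparison asked which genes change when YAP1 and TAZ are lowered, whichever siRNAs are used. The largest shared falls included the known YAP/TAZ targets ANKRD1 (log2 fold change -3.32 ± 0.08 with siYAP/TAZ#1 and -4.07 ± 0.08 with siYAP/TAZ#2), CCN2 (-3.65 and -2.85) and CCN1 (-1.95 and -3.09), the last 2 encoding matricellular proteins. HBEGF, an EGF family growth factor, fell by -1.62 and -1.64, the homeobox gene GBX2 by -1.54 and -1.84, and PPME1, a phosphatase methylesterase, by -1.70 and -2.23. SERTAD4 (-2.07 and -1.87), INSYN2B (-1.99 and -1.81), FAM91A1 (-1.51 and -1.63), KRTAP2-3 (-2.72 and -3.45) and SBDSP1 (-2.21 and -1.50) complete the 12 with YAP1. KRTAP2-3 belongs to a family of near-identical genes and SBDSP1 is a pseudogene, so their values are uncertain. The adjusted p of these genes was at most 7.31e-10 with siYAP/TAZ#1 and at most 2.01e-11 with siYAP/TAZ#2 (edgeR).

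The largest shared rises were in ADORA1, an adenosine receptor (log2 fold change 2.72 ± 0.17 and 2.38 ± 0.17), and BMF, a pro-apoptotic member of the BCL-2 family (2.83 and 2.21). TMEFF2 rose by 1.97 and 2.39, the Hedgehog pathway transcription factor GLI1 by 1.91 and 2.14, and the adhesion molecule VCAM1 by 1.81 and 2.43. The calcium channel gene ORAI3 (1.77 and 1.87), MAP1A (1.74 and 2.00), SNN (1.70 and 1.78), the desmosomal linker PPL (1.86 and 1.59), CD24 (1.92 and 1.51), the carotenoid oxygenase BCO1 (1.54 and 1.51) and the ephrin receptor EPHA4 (1.45 and 1.52) also rose.

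In all, siYAP/TAZ#1 changed 6967 of 15602 genes (3305 rose and 3662 fell) and siYAP/TAZ#2 changed 7604 (3883 rose and 3721 fell). At a change of at least 2-fold these were 343 and 224 with siYAP/TAZ#1, and 472 and 359 with siYAP/TAZ#2. Both combinations changed 4653 genes in the same direction (2321 rose and 2332 fell), and 202 and 69 of these by at least 2-fold in both. Independent lists of these sizes would share 823 rising and 873 falling genes. Unchanged groups simulated against the same controls shared 0 in each of 20 runs. Those runs called at most 1 gene with siYAP/TAZ#1 and 2 with siYAP/TAZ#2, so they cannot measure how much shared controls raise the overlap. With split controls, a count added after seeing the data, 3502 genes were shared on average, 1692 of them rising. Independent lists of the split-control sizes would share 531.7 rising and 621.9 falling genes. Across genes, which are not independent replicates, the 2 profiles correlated with Pearson's r of 0.692 and Spearman's rho of 0.680, against 0.502 and 0.449 in the simulated unchanged groups. Their covariance was 0.155 against 0.0176, a difference of 0.138. With library totals in place of TMM, the median of all genes moved from 0.01 to 0.12 with siYAP/TAZ#1 and from 0.02 to 0.13 with siYAP/TAZ#2, and rises made up 68.4% and 69.6% of calls against 47.4% and 51.1%. Among shared changes the rising share moved from 49.9% to 74% (69.3% with upper-quartile factors), so small changes are read relative to the median gene.

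**Figure D2:**
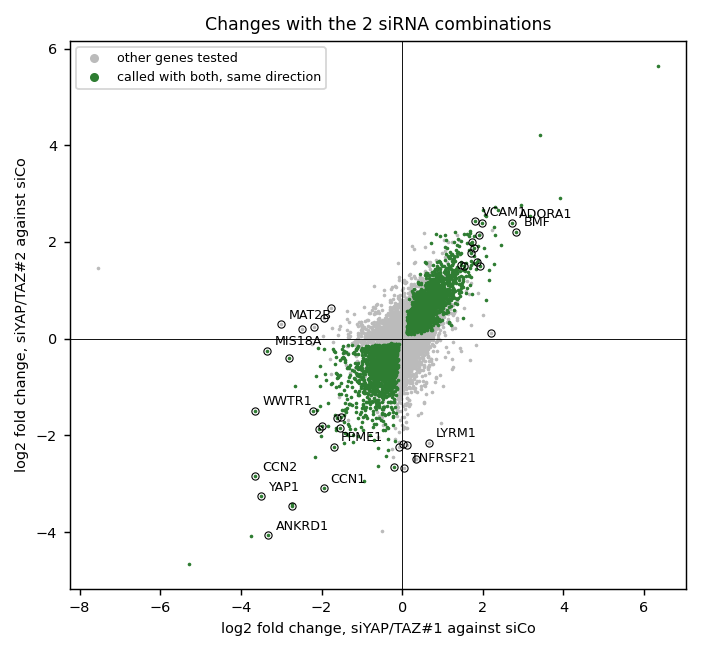
Log2 fold change of each of the 15602 genes tested with siYAP/TAZ#1 (x axis) and siYAP/TAZ#2 (y axis) against siCo; green points are the 4653 genes called with both in the same direction, grey points are other genes, and circles are named genes. ANKRD1, CCN2 and YAP1 fell with both, while MAT2B fell with siYAP/TAZ#1 (-2.999) and TNFRSF21 with siYAP/TAZ#2 (-2.66).

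The list of YAP/TAZ target genes, taken from general knowledge, fell with both combinations. Of its 21 measured members, 19 fell with siYAP/TAZ#1 and 16 with siYAP/TAZ#2 (15 with both), with TGFB2 at -2.03 and -1.39 beside ANKRD1, CCN2 and CCN1. The 1 riser with siYAP/TAZ#1 was RBMS3 (0.22), picked after its values were seen. The counts were the same adjusted over the list alone. This list kept its camera call with an estimated correlation in both (adjusted p = 5.46e-11 and 0.00304 with siYAP/TAZ#1, 1.45e-09 and 0.0051 with siYAP/TAZ#2).

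Genes of the Hippo pathway itself also fell. Of 27, 15 fell with siYAP/TAZ#1 and 16 with siYAP/TAZ#2 (13 with both, and 4 rose with each), led by AMOTL2 (-1.18 and -1.87), FRMD6 (-1.35 and -0.87), the kinase gene LATS2 (-1.19 and -0.81) and WWC1 (-0.48 and -1.45). Several of these encode upstream inhibitors of YAP and TAZ. Of the whole Hippo list, AMOTL2, LATS2 and PTPN14 are on the target list too, so the 2 list results are not separate. Adjusted over the list alone, 16 fell and 5 rose with siYAP/TAZ#1, with the counts for siYAP/TAZ#2 unchanged. The camera adjusted p was 0.000839 and 0.00019, and with an estimated correlation the adjusted p was 0.0927 and 0.0672.

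DNA replication genes fell with each combination, 22 of 36 with siYAP/TAZ#1 and 17 with siYAP/TAZ#2 (23 and 17 adjusted over the list alone), and 13 of them with both, while 21 differed between the combinations. Examples are GINS1 (-1.32 and -0.62) and CDC45 (-0.32 and -1.01) of the replicative helicase, RPA2 (-0.35 and -0.999), and the methylation maintenance factor UHRF1 (-0.97 and -0.70). The camera adjusted p was 2.33e-05 and 0.000554, and 0.274 and 0.355 with an estimated correlation. RRM2 rose with siYAP/TAZ#1 (0.35) and CCNE2 with siYAP/TAZ#2 (0.51), picked after their values were seen. Mitosis genes fell in 16 of 36 cases with siYAP/TAZ#1 and in 8 with siYAP/TAZ#2, where 6 rose (the same adjusted over the list alone). PRC1 was at -0.28 and -0.37, CENPA at -0.31 and -0.17, NDC80 at 0.11 (not called) and 0.48, and CCNA2 at -0.13 (not called, adjusted p = 0.066) and -0.90. With log2(TPM + 1), CENPA was at -0.04 with siYAP/TAZ#2 and not called (limma-trend adjusted p = 0.588). NDC80 was at 0.23 with siYAP/TAZ#1 in that test and called (limma-trend adjusted p = 0.0161). The camera adjusted p was 0.00837 with siYAP/TAZ#1 (0.615 with an estimated correlation, 0.149 with library totals, where the list median was 0.0073 against -0.105) and 0.795 with siYAP/TAZ#2, where the median also turned above 0 under library totals, upper-quartile factors and TPM. Library totals move all genes alike, and the list's distance to the median gene was -0.117 with siYAP/TAZ#1 under both scalings.

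Interferon and double-stranded RNA response genes rose, 16 of 21 with siYAP/TAZ#1, where 1 fell, and 13 with siYAP/TAZ#2 (12 with both, the same adjusted over the list alone). The transcription factor gene IRF9 (0.98 ± 0.06 and 1.17 ± 0.06), IFIT1 (1.10 and 0.53), IFIT3 (0.58 and 0.65) and OAS1 (0.51 and 0.73) are effectors or regulators of that response. The camera adjusted p was 6.22e-05 and 0.000178, and 0.0927 and 0.0672 with an estimated correlation. The controls also received an siRNA, the nonsense one.

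Ribosomal protein mRNAs fell by a small amount, 28 of 32 with siYAP/TAZ#1 and 29 with siYAP/TAZ#2 (27 with both; 31 and 31 adjusted over the list alone). RPL32 was at -0.37 and -0.34, RPL18 at -0.24 and -0.38 and RPL11 at -0.25 and -0.30. The list median was -0.21 and -0.24, or -0.23 and -0.25 relative to the median of all genes, a distance that was -0.23 and -0.25 with library totals as well. With both, 28 members were called under DESeq2 size factors, but only 4 under library totals, 10 under upper-quartile factors and 17 without siCo replicate 3. The shallow library siYAP/TAZ#1 replicate 3 held 3.96% of its counts in ribosomal protein genes against 4.57% to 4.63% in the rest of its group, and 21 members were called with both without it. The camera adjusted p was 2.33e-05 and 9.68e-06, and 0.428 and 0.358 with an estimated correlation of 0.52.

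The other lists moved less uniformly. Mesenchymal markers rose in 6 of 16 cases with siYAP/TAZ#1 (camera adjusted p = 0.0189, and 0.274 with an estimated correlation) and in 8 with siYAP/TAZ#2 (0.0684, and 0.0157 without siCo replicate 1), among them COL3A1 (0.63 and 1.07) and PDGFRA (2.00 and 2.66). PDGFRA stood at 0.08 to 0.33 CPM in the controls, so its change rests on few counts. VIM fell with siYAP/TAZ#1 (-0.19), and ZEB1 (-0.60) and PDGFRB (-0.81) with siYAP/TAZ#2, picked after their values were seen. Of 12 epithelial markers 4 rose with both, led by ELF3 (2.07 and 0.80), and 4 fell with both, led by OCLN (-0.65 and -1.39) and CLDN1 (-0.92 and -1.12), with camera adjusted p of 0.665 and 0.673. Hepatocyte markers held 3 risers and 1 faller of 8 with each, including the urea cycle gene CPS1 (0.97 and 1.29) and the fibrinogen gene FGB (-1.36 and -1.97), with adjusted p of 0.218 and 0.391. Blood and endothelial markers held 1 and 2 risers of 7, at under 1 CPM, with adjusted p of 0.686 and 0.831.

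Glycolysis and hypoxia genes held 5 risers and 6 fallers of 22 with siYAP/TAZ#1 (camera adjusted p = 0.686), and 2 and 10 with siYAP/TAZ#2 (0.00992, with 0.355 at an estimated correlation and 0.0667 with library totals). Hexokinase gene HK2 fell by -1.09 and -0.89, the glucose transporter gene SLC2A1 by -0.52 and -0.66 and ADM by -0.99 and -1.73, while PFKFB4 rose by 1.08 and 0.95. Stress response genes held 6 risers and 7 fallers of 20 with siYAP/TAZ#1 (0.686), and 4 and 10 with siYAP/TAZ#2 (0.0426, with 0.355 at an estimated correlation, 0.0853 with library totals, 0.0626 without siCo replicate 3 and 0.0637 without siYAP/TAZ#2 replicate 1). The chaperone gene HSPA5 was at -0.89 and -0.18, and PPP1R15A at -0.77 and -0.97. With log2(TPM + 1) the siYAP/TAZ#2 value of HSPA5 was -0.05 and not called (limma-trend adjusted p = 0.296). Of 20 p53 targets 7 rose and 6 fell with siYAP/TAZ#1 and 8 and 5 with siYAP/TAZ#2 (camera adjusted p = 0.823 and 0.928), with CCNG1 at 1.13 and 0.80, and MDM2 at -0.39 and -1.20. Of 30 focal adhesion and matrix genes 6 and 7 rose and 10 and 10 fell (0.517 and 0.199), such as COL1A1 (0.78 and 0.43) and PARVA (-0.71 and -0.49). Of 19 actin and SRF genes 4 and 4 rose and 4 and 6 fell (0.823 and 0.673), such as MYL9 (0.41 and 0.42) and FHL2 (-0.56 and -0.52). With siYAP/TAZ#2 the median of the actin genes was 0.02 and the test's direction down, the median of the p53 targets was 0.07 and the mean -0.03, and the median of the epithelial markers was 0.17 with the test's direction down. Under library totals, upper-quartile factors and TPM the median turned from below to above 0 for focal adhesion genes with both, for glycolysis and stress genes with siYAP/TAZ#1 and for blood markers with siYAP/TAZ#2, and under TPM for glycolysis genes with siYAP/TAZ#2. Library totals and upper-quartile factors move all genes alike, and relative to the median gene these lists stayed where they were: -0.02 and -0.08 for focal adhesion genes, -0.04 for glycolysis and -0.09 for stress genes with siYAP/TAZ#1, under TMM and library totals. The counts for these lists adjusted over the list alone were the same or differed by 1.

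**Figure D3:**
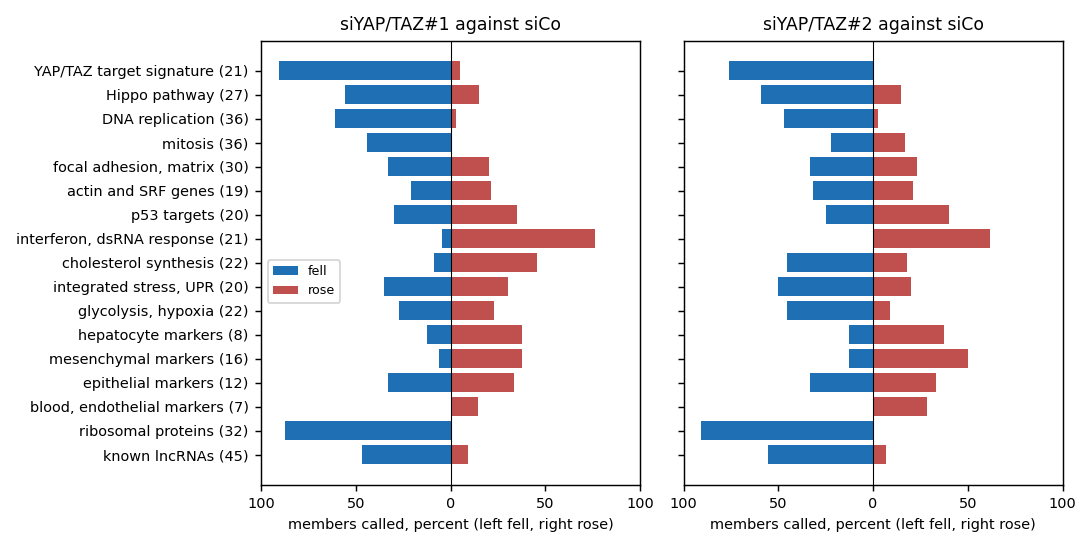
Share of the measured members (number in brackets) of each gene list that fell (left, blue) or rose (right, red) at an adjusted p under 0.05 with siYAP/TAZ#1 and siYAP/TAZ#2 against siCo (edgeR, TMM scaling). The YAP/TAZ target list fell in 19 and 16 of 21 cases, and the ribosomal protein list in 28 and 29 of 32, where 4 were called with both under library totals.

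The second comparison asked which lncRNA genes change with YAP1 and TAZ, the subject of the series title. PLCE1-AS1 (Entrez 100128054) fell the most of the named lncRNA genes, from 6.34 ± 0.82 CPM in the controls to 0.45 ± 0.13 and 0.37 ± 0.09 (log2 fold change -3.74 ± 0.19 and -4.08 ± 0.19, edgeR adjusted p = 2.24e-11 and 4.56e-12). LINC02901 (-1.33 and -1.75), LNCOC1 (-0.97 and -1.10), SNHG15 (-0.97 and -1.28), TEX41 (-0.86 and -0.99), MIR4435-2HG (-0.80 and -1.09), MAMDC2-AS1 (-0.83 and -1.06) and CFLAR-AS1 (-1.02 and -0.79) also fell. CYP1B1-AS1 (1.18 and 1.26), LINC00173 (1.73 and 0.93), DNM3OS (1.21 and 0.90), LINC02525 (1.17 and 0.94), EPHA5-AS1 (0.92 and 0.90), ZNF561-AS1 (0.88 and 0.92), LOC100128288 (0.86 and 0.97) and STARD4-AS1 (0.98 and 0.84) rose.

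Of 1125 lncRNA genes tested, siYAP/TAZ#1 changed 227 and siYAP/TAZ#2 283. Both changed 143 in the same direction, of which 85 rose and 58 fell (112, with 64 and 48, adjusted over the lncRNA genes alone), where independent lists would share 20 and 9. With split controls, which leave fewer control libraries per contrast and so fewer calls, the shared count was 94.5 on average. Under library totals it was 198 with 157 rising, under upper-quartile factors 184 with 138 rising and under TPM 186 with 142 rising, so the balance of rises and falls depends on the scaling. In the list of 45 known lncRNAs, 21 fell with siYAP/TAZ#1 and 25 with siYAP/TAZ#2 (21 and 25 adjusted over the list alone). NEAT1 (0.43), TUG1 (0.18), MIR503HG (0.52) and TP53TG1 (0.65) rose with siYAP/TAZ#1, and MIR503HG (0.53), TP53TG1 (0.58) and MILIP (0.36) with siYAP/TAZ#2, picked after their values were seen. MIR100HG was at -0.59 and -1.38 and SNHG16 at -0.49 and -1.31, and the list's camera adjusted p was 0.00225 and 3.76e-05, and 0.0927 and 0.0349 with an estimated correlation. The median lncRNA gene stood at 1.82 CPM against 26.4 for protein-coding genes. Over 347 pairs of an antisense lncRNA and the gene it is named for, the log2 fold changes correlated with a Spearman rho of 0.299 and 0.276 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give), which shared counts or a joint response would each give. PLCE1 itself rose (0.38 and 0.26), opposite to PLCE1-AS1, and WWTR1-AS1 was at 0.43 and 0.11 where WWTR1 fell, picked after its values were seen.

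**Figure D4:**
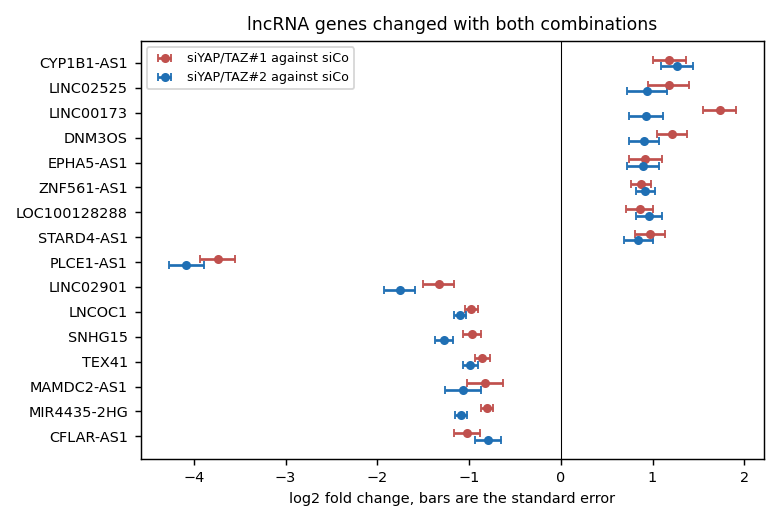
Log2 fold change with its standard error for the 16 named lncRNA genes with siYAP/TAZ#1 (red) and siYAP/TAZ#2 (blue) against siCo, 4 libraries per group. PLCE1-AS1 fell by -3.74 and -4.08, and the 8 named risers lie between 0.84 and 1.73.

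The third comparison set the 2 combinations against each other. Genes lower with siYAP/TAZ#1 included MAT2B, a regulatory subunit of methionine adenosyltransferase (log2 difference -3.30; -2.999 against control with siYAP/TAZ#1 and 0.30 with siYAP/TAZ#2), and the centromere gene MIS18A (-3.11; -3.35 and -0.24). RBMS1 (-2.68), CENPQ (-2.42), CNIH1 (-2.40), the mitochondrial transcription factor gene TFAM (-2.40), the pyruvate carrier gene MPC2 (-2.36) and WWTR1 (-2.15) complete the 8. Genes lower with siYAP/TAZ#2 included the cell-cycle factor E2F5 (log2 difference 2.83; 0.33 with siYAP/TAZ#1 and -2.49 with siYAP/TAZ#2), LYRM1 (2.81), the death receptor gene TNFRSF21 (2.71; 0.05 and -2.66) and OSTM1 (2.46). CLDN12 (2.32), TMTC3 (2.22) and DDAH1 (2.15) followed, and the adjusted p of these 15 genes was at most 3.61e-13 (edgeR). The read-through gene PHOSPHO2-KLHL23 (2.08, edgeR adjusted p = 0.0134) is uncertain: its adjusted p was 0.052 without siYAP/TAZ#1 replicate 4, 0.253 with the DESeq2 Wald test, 0.173 with glmTreat and 0.0863 with log2(TPM + 0.1).

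The direct test called 5134 genes, 2349 higher and 2785 lower with siYAP/TAZ#1. Cholesterol synthesis genes differed, with 16 of 22 higher and 3 lower with siYAP/TAZ#1 (the same adjusted over the list alone, camera adjusted p = 0.00272, and 0.194 with an estimated correlation). Against controls, 10 rose and 2 fell with siYAP/TAZ#1 (12 and 2 adjusted over the list alone), and 4 rose and 10 fell with siYAP/TAZ#2. The regulator gene SREBF2 was at 0.49 and -0.77 (difference 1.26), picked after its values were seen, while FDFT1 rose with both (0.44 and 0.22) and SQLE fell with both (-0.99 and -0.33). Epithelial markers were higher with siYAP/TAZ#1 in 6 of 12 cases (7 adjusted over the list alone; camera adjusted p = 0.0142, and 0.194 with an estimated correlation), led by ELF3 (1.27), mitosis genes lower in 16 of 36 and higher in 3 (0.0296, and 0.83), glycolysis genes higher in 5 of 22 and lower in 1 (0.0296, and 0.713), and known lncRNAs higher in 13 of 45 and lower in 3 (0.0269, and 0.229). The members in the smaller of these counts, picked after their values were seen, are CCNA2 (0.77), PLK1 (0.13) and BIRC5 (0.18) for mitosis, HK2 (-0.20) against ADM (0.74), NDRG1 (0.70), VEGFA (0.61), PFKFB3 (0.36) and ENO2 (0.27) for glycolysis, and OIP5-AS1 (-0.39), LINC01116 (-0.30) and TMPO-AS1 (-0.27) for the lncRNAs. The cholesterol list's camera adjusted p against controls was 0.0352 with siYAP/TAZ#1 (0.274 with an estimated correlation, 0.0736 without siCo replicate 1, 0.0663 and 0.0546 without siYAP/TAZ#1 replicates 2 and 4) and 0.0762 with siYAP/TAZ#2 (0.0379 without siCo replicate 1). The median of the cholesterol list with siYAP/TAZ#2 was -0.08, and above 0 under library totals, upper-quartile factors and TPM, with a distance to the median gene of -0.09 under TMM and library totals. For the mitosis list, siYAP/TAZ#2 replicate 2 stood apart, with a list mean of 8.02 log2 CPM against 7.88 to 7.9 in the rest of its group. The direct list test was not rerun without that library.

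Short sequences in the 3' UTRs also separated these genes. Of 106 genes with a UTR that were at least 2-fold lower with siYAP/TAZ#1 and fell with it, 51.9% held the 7-mer GGAACTT against 16.3% of genes of like UTR length (binomial adjusted p = 6.71e-13), among them MAT2B, RBMS1, CENPQ and MPC2. Of 157 such genes for siYAP/TAZ#2, 54.8% held CTTCTTA against 18.4% (3.64e-20), among them E2F5, LYRM1, TNFRSF21, OSTM1, CLDN12 and TMTC3. In the 57 genes that fell at least 2-fold with both, the shares were 17.5% against 9.50% and 15.8% against 11.8%, and the binomial test with adjustment called 0 7-mers there (5 with the normal tail). Over all 2103 genes with a UTR that fell with both, GGAACTT stood at 13.6% against 10.4% and CTTCTTA at 16.8% against 13% (binomial p = 1.11e-06 and 4.91e-07, not adjusted), so shared falls are not free of these 7-mers. Genes of the sets that gave the 7-mers, such as OSTM1, were not removed from the 2103. These p-values are therefore not a separate test.

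**Figure D5:**
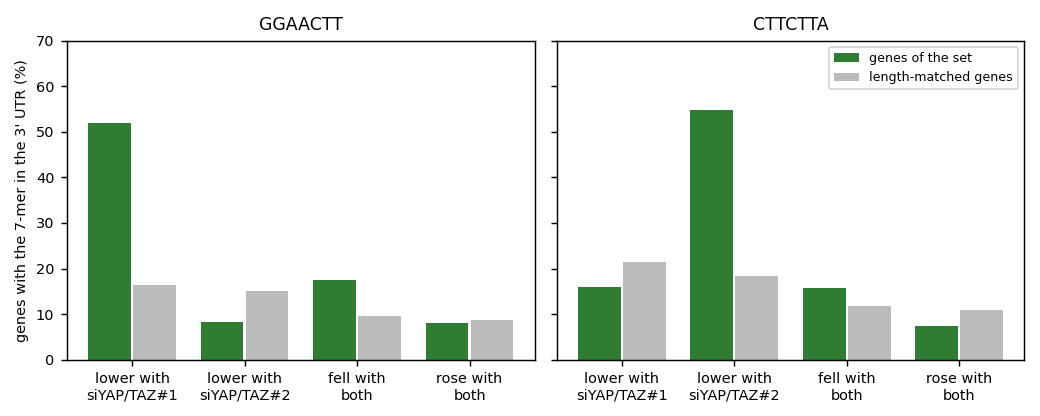
Percent of genes whose 3' UTR holds GGAACTT (left) or CTTCTTA (right), in genes at least 2-fold lower with one combination than with the other, and in genes that fell or rose at least 2-fold with both; grey bars are the shares in genes of like UTR length. GGAACTT stands at 51.9% in the genes lower with siYAP/TAZ#1 and 8.28% in those lower with siYAP/TAZ#2, and CTTCTTA at 16% and 54.8%.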

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

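The comparison with WWTR1 loss, the binomial tail for the 7-mers, and the library-total and upper-quartile scalings were chosen only after the results they test were seen, and the comparison with abundant mRNAs after the ribosomal fall was seen. The genes that set the 2 siRNA combinations apart form the first pattern. In the 2 contrasts with control, 377 genes changed in opposite directions. Such genes differ in the direct test almost by construction, and all of them did. MAT2B, MIS18A, RBMS1, TFAM and MPC2 fell far more with siYAP/TAZ#1 than with siYAP/TAZ#2 or fell with it alone, and E2F5, LYRM1, TNFRSF21 and OSTM1 the reverse. Small RNAs can silence mRNAs whose 3' UTR matches their seed, and this might explain part of these falls: the 7-mer GGAACTT was 3.18 times as frequent as in genes of like UTR length in the genes lower with siYAP/TAZ#1, and CTTCTTA 2.98 times in those lower with siYAP/TAZ#2. Each 7-mer was at or below its matched share in the other set (16% against 21.5% for CTTCTTA, and 8.28% against 15% for GGAACTT). GGAACTT occurs in the WWTR1 mRNA and CTTCTTA in both target mRNAs, but 40.4% of all 7-mers occur in one of them, and the siRNA sequences were not used here. CTTCTTA was also frequent in genes that rose with siYAP/TAZ#1 and were lower with siYAP/TAZ#2 (58.6% against 19.8%), GGAACTT in genes that rose with siYAP/TAZ#2 and were lower with siYAP/TAZ#1 (32% against 13%, not called, adjusted p = 0.278 in the binomial test), and genes such as MIS18A and TFAM hold neither 7-mer. These sets of risers overlap the sets of fallers and are not separate from them. With or without a UTR, 67 risers and 168 fallers lie within the same 192 genes at least 2-fold higher with siYAP/TAZ#1 than with siYAP/TAZ#2. Likewise 77 risers and 109 fallers lie within the same 146 genes at least 2-fold lower with siYAP/TAZ#1. The test also called 24 7-mers (123 with the normal tail) in genes that rose at least 2-fold with both.

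A graded response to the deeper WWTR1 loss could also lower genes with siYAP/TAZ#1. It cannot be told apart here: the 109 genes had a median of -1.19 with siYAP/TAZ#1 and 0.122 with siYAP/TAZ#2, but they were selected for a difference of at least 2-fold, which alone keeps the second median above about -0.19. Without the shallow library siYAP/TAZ#1 replicate 3, 100% of these genes were still called lower in the direct test. That call therefore does not rest on this library. The rerun asked for neither the 2-fold difference nor the fall against control, so it cannot show whether the library shaped the set.

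The second pattern is the small fall of ribosomal protein mRNAs such as RPL32, RPL18 and RPL11 with both combinations. Scaling may account for how many pass the threshold, because the lowest number called with both over 3 other scalings was 4 of 32, against 27. That was under library totals, while 10 were called under upper-quartile factors and 28 under DESeq2 size factors. The distance of the list to the median gene stayed at -0.23 and -0.25 under library totals. A shift of all abundant mRNAs cannot be told apart from a change in this list: its median lay at the 3.04th percentile of abundance-matched random lists with siYAP/TAZ#1 and at the 0.34th with siYAP/TAZ#2, where the random lists had medians of -0.14 and -0.11. The lower bound of the random lists, -0.22 with siYAP/TAZ#1, lies beside the list's -0.21, which keeps this open.

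In 5 lists the 2 combinations differed in the direct test, with camera adjusted p of 0.00272 for cholesterol synthesis, 0.0142 for epithelial markers, 0.0269 for known lncRNAs, and 0.0296 each for mitosis and for glycolysis and hypoxia genes. With an estimated correlation these were 0.194, 0.194, 0.229, 0.83 and 0.713.

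Single libraries lay far from the other 3 of their group (Dixon's test) in 41 of 414 groups tested, where chance gives 20.7. Of these, 9 were in the shallow library siYAP/TAZ#1 replicate 3: the ribosomal share (3.96% of counts), the ribosomal list mean (9.07, in log2 CPM as are all values that follow), YAP1 (4.58 against 4.22 to 4.24), EPHA5-AS1 (1.99), LOC100128288 (2.5), MAMDC2-AS1 (0.089), AEN (5.45), SLC2A1 (5.16) and RPL32 (8.29). In siYAP/TAZ#1 replicate 1 they were PPME1 (7.90), OSTM1 (6.91) and MSMO1 (5.83), and in replicate 2 the focal adhesion list mean (6.88) and CD14 (-2.12). In siYAP/TAZ#2 replicate 2 they were the mitosis list mean (8.02), LINC02525 (0.60), LATS2 (5.77), NDC80 (8.34), MYL9 (8.64), CCNG1 (7.28), HSPA5 (10.2) and RPL18 (8.26). PDGFRA (0.80) stood apart in siYAP/TAZ#2 replicate 1, and PHOSPHO2-KLHL23 (-3.80), HERPUD1 (5.09) and KDR (-0.17) in replicate 3. Among the controls these were CD24 (4.87), STARD4-AS1 (0.79), TMTC3 (7.66), SQLE (6.69) and HERPUD1 (5.44) in replicate 1, ELF3 (0.57) in replicate 2, and KRTAP2-3 (3.45), INSYN2B (5.77), LNCOC1 (4.97), CFLAR-AS1 (2.27), DDAH1 (6.33) and RPL11 (9.88) in replicate 3. COL1A2 (-2.05), COL3A1 (5.05) and KDR (-0.55) stood apart in siCo replicate 4.

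Among the 35 ways to split the 8 libraries of 2 groups into 4 and 4, only 1, the real one, gave as many calls for siYAP/TAZ#1 (6967, highest other 1), for siYAP/TAZ#2 (7604, highest other 1) and for the direct contrast (5134, highest other 1). Every other split put libraries of both groups on each side, which widens the spread within a side. Their low counts therefore do not measure how many calls unchanged libraries would give. Over 100 splits of all 12 libraries, the real one included, only 1 gave 4653 shared genes or 143 shared lncRNA genes (highest other 0 for both). The other splits there mix the groups too. In the same splits 3 others called 4042, 2528 and 1659 genes for one combination against control, and 2545, 2438 and 2992 in the direct contrast.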

How the results depend on the processing

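The counts of changed genes stayed within 1.5 times under DESeq2 size factors, other filters, the DESeq2 Wald test, limma-voom and TPM. They also did so under library totals and upper-quartile factors, chosen after seeing the data. In these settings the target falls kept their direction and side of the threshold, but they were not evaluated under the other count filters. The members and the balance of rises and falls moved more: of the 4653 shared genes, 3655 were still called with both under library totals, 3840 under upper-quartile factors and 3274 under TPM, where the rising share was also higher. With glmTreat, which tests for changes above 1.5-fold and so calls fewer genes by construction, the counts were 711 for siYAP/TAZ#1, 1125 for siYAP/TAZ#2, 520 for the direct contrast, 340 shared genes and 10 shared lncRNA genes. The list count stayed at 6 under DESeq2 size factors, library totals and the replicate block, and was not run with other filters, the Wald test, limma-voom, TPM or upper-quartile factors. The 6 lists called with both combinations became 1 with an estimated correlation, which ran from -0.012 to 0.52 over the lists against the preset 0.01. With fry the count was 11, but fry asks whether a list changed at all, not whether it changed more than other genes. The 6 and the 11 are therefore not counts of the same thing, and no cause was tested. The correlation of 0.692 became 0.635 at a mean log2 CPM of at least 2. It was 0.552 with the controls split into pairs, which removes the shared controls but also leaves fewer control libraries per contrast. The covariance was then 0.139, against 0.155. Leaving out 1 library in turn gave 6242 to 7463 genes for siYAP/TAZ#1, 7003 to 7915 for siYAP/TAZ#2, 4611 to 5082 in the direct contrast, 4167 to 5069 shared, 123 to 148 shared lncRNA genes, 6 to 7 lists and a correlation of 0.66 to 0.709. YAP1 ran from -3.59 to -3.48 and from -3.29 to -3.22, and WWTR1 from -3.67 to -3.605 and from -1.525 to -1.47. With the replicate number as a block the counts were 6879, 7530, 4999, 4597 and 137; 5 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs. Of 6066 values for named genes over 25 alternatives, 202 fell short of the threshold (87 results) and 36 passed it anew (9 results). No value called in the main test or in the alternative changed sign. Sign changes of values called in neither were not counted. Fewer genes of low count were called, with no test of depth itself: both combinations changed 9.22% of protein-coding genes at a mean log2 CPM of at most 0, and 36.8% above 4.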

Other observations

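The host comparison and the comparison with other short genes were chosen after the snoRNA falls were seen. Small nucleolar RNAs guide chemical modification of ribosomal RNA and are mostly cut from introns of host genes, such as SNHG15 and SNHG16, that fell here. Of 162 snoRNA genes tested, 55 fell with siYAP/TAZ#1 and 81 with siYAP/TAZ#2, and 48 fell with both, where independent lists would share 28 (edgeR adjusted p under 0.05). Both contrasts share the controls, which can raise the overlap by itself, and snoRNA genes were not counted with split controls. Their medians were -0.41 and -0.52, and ran from -0.41 to -0.30 and from -0.53 to -0.39 under other scalings. Counting of short genes might lower all short RNAs alike, but 57 other short genes, mostly miRNA genes, had medians of -0.16 and -0.21, and the smaller of the 2 differences to snoRNA genes was 0.255. Lower host transcripts could carry part of the fall: for 151 snoRNA genes within one of 83 hosts (strand not considered), snoRNA and host changes correlated with a Spearman rho of 0.167 and 0.327 (p = 0.0414 and 6e-05; snoRNAs of one host are not independent). The hosts had medians of -0.23 and -0.25, and whether mature snoRNAs or host reads were counted stays open.

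The share of lncRNA genes called with both combinations differed by abundance. Above a mean log2 CPM of 4, both combinations changed 35.6% of 104 lncRNA genes and 36.8% of 8341 protein-coding genes in the same direction, while over all abundances the shares were 12.7% and 32%. From 2 to 4 they were 20.6% and 35.7%, and from 0 to 2 10.9% and 22.5%.

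The changes of antisense lncRNA genes and the genes they are named for correlated weakly, with the lower of the 2 Spearman rho at 0.276. PLCE1-AS1 fell with both combinations while PLCE1 rose, by 0.257 at the lower of its 2 changes, a comparison chosen after seeing the values.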
